A study of Mus musculus with 4 samples.

How the data were processed

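FAIRE DNA and input DNA came from cultured cancer cells of hyperglycemic MMTV-PyMT/PANIC mice and euglycemic MMTV-PyMT mice, per the source labels. They were sequenced as single-end libraries on a SOLiD instrument, per the labels' protocols and design text, with 1 library of each kind per condition. Peaks were called with MACS on mm9, per the submitters' processing notes. The aligner, the MACS settings, any filter on duplicate or multiply mapped reads, and the choice of treatment and control libraries are not given in the sources used here. Each of these bears on the list: a peak called against input marks open chromatin in a sample, whereas a peak called against the other condition marks a difference, and the list alone does not tell which was done.

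The deposited list gives a chromosome, start, end, name and score for each of 3190 peaks. The score is the authors' own value per peak from their peak caller. Its scale is not given in the sources used here; MACS conventionally writes 10 times the negative log10 of the p-value, and the lowest value was 50.01. It was used only to describe, rank and filter peaks within the list. Peak names ran from 1 to 3190 with none missing, and no neighbouring peaks overlapped. The list's starts count from 0 and were printed from 1. The mitochondrial peak had a start of -165, before the beginning of the sequence, and was clipped to the first base. Read counts per library were not used here, so read depth is unknown and no interval for any peak's enrichment was given. Intervals on numbers of peaks cover counting error only.

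No genome sequence, chromosome lengths or gene annotation of mm9 were used. The gene table at hand was of GRCm38.p6, and 22 peaks ended beyond the last gene of that table on their chromosome. That count alone does not show a mismatch, since peaks can lie beyond the last gene in a matching build. Because the table was of another build than mm9, its coordinates were not used to place peaks at genes. The planned shares of peaks at transcription start sites and in gene features, the 13 gene lists fixed beforehand (ErbB ligands and receptors, glycolysis, insulin signalling, inflammation, chromatin modifiers, cell type markers and others) and the neuregulin 1 locus were not analysed for this reason.

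Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Intervals of medians came from binomial order statistics. The correlation of width with score used 100000 permutations. Peak density was taken over the span from the first to the last peak of each chromosome, which replaced chromosome length; this choice and the shuffle of bins of about 10 Mb among chromosomes (100000 permutations) were made after the data were seen. Span is a lower bound of length. Clustering was measured as the number of peaks whose gap to the nearest other peak was at most 10 kb, against 1000 placements of the same widths, without overlap, between the first and the last peak of each chromosome. This test, with fewer placements per set, was tried on simulated data of 3189 peaks: it passed 0.05 in 1 of 20 sets placed at random and in 20 of 20 sets with 100 planted close pairs. The simulated sets were drawn in the same way as the test's own placements. They check the calculation only, and do not cover uneven density, assembly gaps or mappability. Windows of 1 Mb were counted on a fixed grid by peak midpoint.

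The peaks named were set by a rule written before the data were examined: the 10 highest scoring and the 5 widest peaks, and the 5 densest windows of 1 Mb, extended to 6 by a tie. Because no gene could be assigned, the parts of that rule on genes named none. Alternatives fixed before the data were examined were score minimums at the median and the upper quartile, merging of peaks within 1 kb or 10 kb, autosomes only, and distances of 2 kb and 100 kb. Alternatives added afterwards were the bin shuffle, placement within each peak's own window of 1 Mb, random placement for the numbers of empty and densest windows, 1 region per cluster, and leaving out the densest windows, the X chromosome, the mitochondrial peak or the 2 peaks farthest from the median width.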

Results

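Open chromatin was profiled in cancer cells from mice of the MMTV-PyMT mammary tumour model, in which a viral promoter drives the polyomavirus middle T antigen, on the FVB background. The assay was FAIRE-seq, which crosslinks chromatin with formaldehyde and recovers the DNA that stays soluble, enriching for stretches with few nucleosomes such as promoters and enhancers. The design paired 2 conditions, cells from hyperglycemic and cells from euglycemic mice, each with 1 FAIRE library and 1 input DNA library, for 4 libraries in all. The source labels give MMTV-PyMT/PANIC mice for the hyperglycemic cells and MMTV-PyMT mice for the euglycemic cells, so the mouse line varies together with the glucose state. The cells had been isolated fresh and cultured without further treatment. A comparison of the conditions would therefore ask whether open chromatin differs after culture, and could not separate glucose exposure from mouse line. The series title names neuregulin 1 and the HER receptors as the axis of interest. The data used here were 1 peak list deposited with the series and tied to no single library. The list does not state which library or libraries its peaks came from or which served as the control, and read depth is unknown. The values below therefore describe that list: no value could be attributed to hyperglycemic or euglycemic cells, no difference between the conditions was tested, and there were no replicates.

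The list held 3190 regions reported by the peak caller, or peaks, that together covered 2.58 Mb of the mm9 genome. Of these, 3157 lay on the 19 autosomes, 32 on the X chromosome and 1 on the mitochondrial genome, and no region was listed on the Y chromosome or on unplaced sequence. The regions were short, with a median width of 779 bp (95% interval of the median over regions 771 to 788 bp, quartiles 644 and 921 bp). The narrowest nuclear region spanned 343 bp and the widest 2401 bp. Scores started at 50.01. The median score was 64.42 (95% interval of the median 63.63 to 65.24), 388 regions (12.2%) reached 100 and 8 regions (0.25%) reached 200. Wider regions scored higher across the list (Pearson r = 0.54 and Spearman rho = 0.41 across 3190 regions, permutation p = 1e-05 for each, the smallest that 100000 permutations can give), with regions of one list not being independent replicates. Width and score were both set by the same peak caller. Part or all of the relation may therefore come from the calling itself, which the permutation cannot tell apart. The higher Pearson's r rested on the single mitochondrial region: without it r was 0.397, and Spearman's rho stayed at 0.41. Pearson's r was 0.39 without the 2 regions farthest from the median width. Among the 1597 regions at or above the median score, Spearman's rho was 0.289.

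The highest score by a wide margin, 1704.78, belonged to the single mitochondrial region, which covered positions 1 to 6588. Mitochondrial DNA is present in many copies per cell and is not packaged in nucleosomes. Whether either trait accounts for the score was not tested, and the control library is not known. Among nuclear regions, the highest score was 246.65, on chromosome 10 at 27583064 to 27583961. It was followed by a region on chromosome 18 at 47390017 to 47390847 with a score of 243.48 and by a second region on chromosome 10, at 40230386 to 40232671, with a score of 230.02. That second region, 2286 bp long, was also among the widest of the list. The remaining regions of the 10 highest lay on chromosome 7 at 134352159 to 134353109 (score 219.47), chromosome 10 at 88433459 to 88434641 (215.27), chromosome 16 at 25904949 to 25906220 (211.07), chromosome 4 at 80617415 to 80618348 (210.95), chromosome 13 at 34203917 to 34205071 (199.43) and chromosome 7 at 133540225 to 133540960 (188.76). The widest nuclear region lay on chromosome 8 at 8273405 to 8275805, with a score of 148.77. A region of 2256 bp on chromosome 10 at 95700109 to 95702364 scored 100.05, and one of 2201 bp on chromosome 6 at 129185327 to 129187527 scored 112.4. Gene annotation of the mm9 build was not used here, so these positions were not assigned to genes, exons or promoters, and the neuregulin 1 locus was not examined.

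The X chromosome carried far fewer regions than any autosome. Its density was 0.209 regions per Mb of the span from its first to its last region (95% Poisson interval 0.143 to 0.294), against 1.34 per Mb over the autosomes, a ratio of 0.156 (95% exact binomial interval 0.107 to 0.221). Autosomes ranged from 1.04 regions per Mb on chromosome 8 (0.873 to 1.24) to 1.95 on chromosome 19 (1.61 to 2.35). Chromosomes 11, 13, 10 and 3 followed chromosome 19, with 1.81, 1.78, 1.72 and 1.63 regions per Mb. In two-sided exact binomial tests of each chromosome's share of regions against its share of the summed span, adjusted by Benjamini-Hochberg over 20 chromosomes, X lay below its share (adjusted p = 1.4e-47) and chromosomes 3, 10, 11, 13 and 19 lay above theirs (adjusted p from 3.7e-06 to 0.00029). The summed span included X, which held 32 regions against 194.43 expected. This lowered the number expected on every autosome, which favours autosomes above their share and hides those below. Against the autosomal mean of 1.34 per Mb, the Poisson intervals of chromosomes 3, 10, 11, 13 and 19 lay wholly above. Those of chromosomes 1, 4, 8, 12 and 14 lay wholly below. Among regions at or above the median score, chromosome 11 no longer passed the exact binomial test (ratio to its share 1.19 against 1.43 over all regions, adjusted p = 0.19). These tests treat neighbouring regions as independent. When 251 bins of about 10 Mb were shuffled among chromosomes instead, X still differed from the other chromosomes (adjusted permutation p = 0.0002, the smallest these permutations can give), and no autosome did (smallest adjusted p = 0.0696, for chromosome 11). At an unadjusted permutation p under 0.05 the bin shuffle gave 6 chromosomes, X included. The other bins set against each autosome included those of X, which lowered their mean. The shuffle can therefore also hide autosomes of low density.

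**Figure D1:**
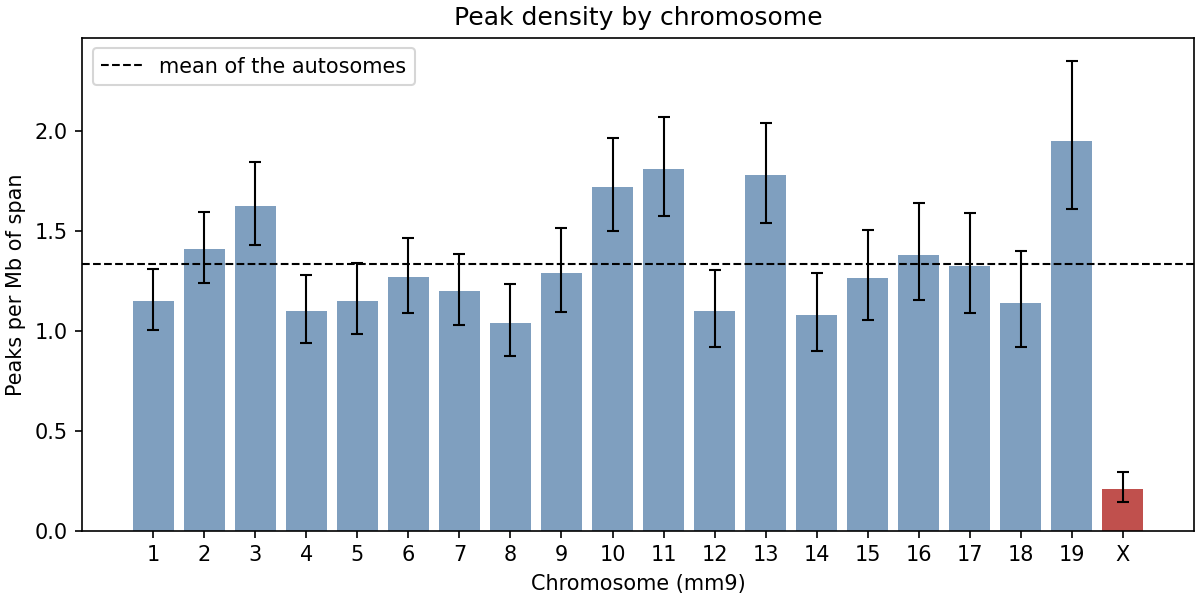
Regions of the peak list per Mb of the span from the first to the last region (vertical axis) on each chromosome (horizontal axis). Error bars are 95% Poisson intervals that cover counting error only, and the dashed line is the autosomal mean of 1.34 per Mb. X, at 0.209 per Mb, lies below all 19 autosomes.

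Regions lay close together more often than random placement gave. Of 3189 nuclear regions, 401 (12.6%) had another region within 10 kb, whereas 1000 random placements of the same widths on the same chromosome spans gave 86.2 ± 13.0 (SD over placements), with a highest value of 128. The ratio was 4.65 (two-sided permutation p over placements = 0.002, the smallest that these placements can give). When each region was instead placed within its own 1 Mb window, which keeps the unevenness over megabases, random placement gave 155 ± 17.2 and the ratio was 2.58 (two-sided permutation p over placements = 0.002). The 401 regions formed 179 pairs, 13 triplets and 1 group of 4, which lay on chromosome 5 between 73955204 and 73959461. The excess was present at shorter and longer range, with 116 regions within 2 kb of another against 17.1 ± 5.77 at random and 1589 within 100 kb against 757 ± 31.3. The random placements ignored assembly gaps and stretches to which reads cannot be mapped uniquely, neither of which was known here.

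**Figure D2:**
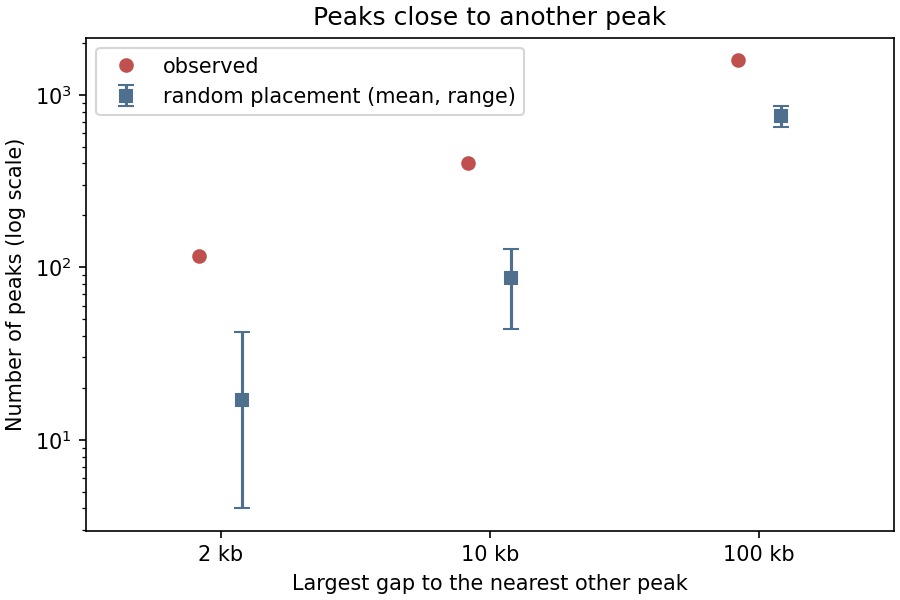
Number of nuclear regions (vertical axis, log scale) whose gap to the nearest other region is at most 2, 10 or 100 kb (horizontal axis), as observed and in 1000 random placements, shown as their mean with bars from the lowest to the highest. The observed 401 regions at 10 kb lie above the highest random value of 128.

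Regions were also unevenly spread over megabases. Of 2382 windows of 1 Mb within the spans of the autosomes, 1050 (44.1%) held no region, against 651 ± 15.5 (27.3%) under random placement, and the 343 densest windows together held at least 50% of the autosomal regions, against 529 ± 8.77 windows under random placement (two-sided permutation p over placements = 0.002 for each, the smallest that 1000 placements can give). The densest window, on chromosome 5 from 91000001 to 92000000, held 15 regions with a median score of 79.8 and a highest score of 162.07. Its neighbouring windows held 0 and 1. Most of its regions lay within 10 kb of another, such as 91465516 to 91466372 beside 91466539 to 91468100. Random placement gave a densest window of 7 regions in the median draw and of 10 at most (one-sided permutation p over placements = 0.001, the smallest that 1000 placements can give). Those placements did not keep close neighbours together, so this count is not separate from the clustering within 10 kb. The next windows were chromosome 13 from 111000001 to 112000000 with 11 regions, chromosome 15 from 59000001 to 60000000 with 10, and 3 windows with 9 each: chromosome 15 from 61000001 to 62000000, chromosome 10 from 21000001 to 22000000, and chromosome 7 from 119000001 to 120000000.

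**Figure D3:**
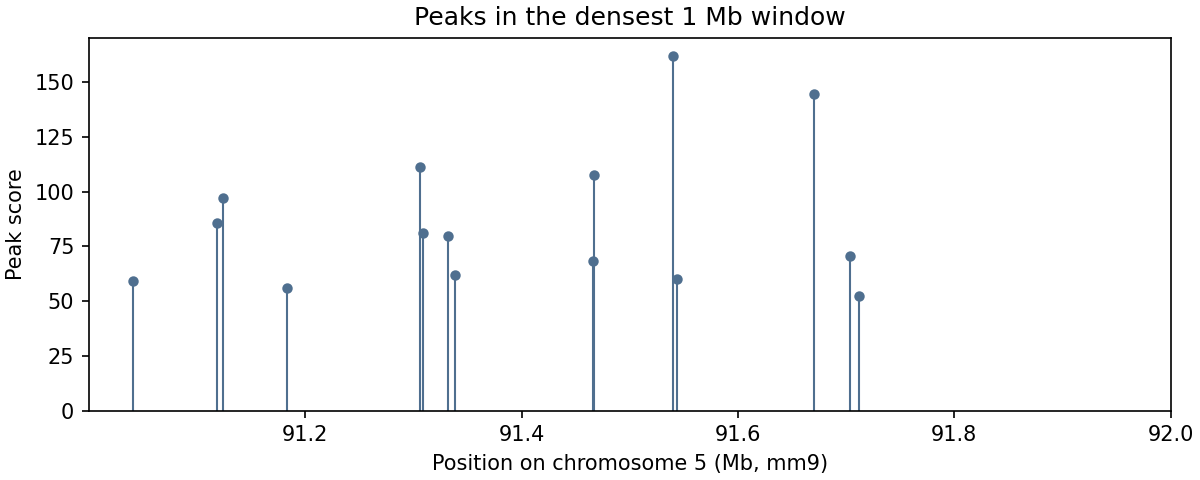
Score (vertical axis) of each of the 15 regions in the densest 1 Mb window against its midpoint on chromosome 5 (horizontal axis, Mb, mm9). The highest, at 162.07, lies at 91539159 to 91539995.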

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

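No paired analysis was possible because each group had 1 library and the list carries no values per library; for the same reason no library could be left out. Keeping scores at or above the median left 1597 peaks over 1.419 Mb, with a median width of 857 bp and a median score of 80.99, and keeping the upper quartile left 798 peaks over 0.759 Mb; fewer peaks follow from the filter itself. Shuffling bins of about 10 Mb, an alternative added after the data were seen, reduced the chromosomes past the threshold from 6 to 1, X alone. At or above the median score 5 chromosomes passed, chromosome 11 being lost with a ratio to its share of 1.19 against 1.43 and an adjusted exact binomial p of 0.19. The X density ratio, the clustering ratio and the correlation of width with score kept direction and side of the threshold under each alternative run: the ratio of X to autosomal density was 0.117 at or above the median score and 0.167 after merging within 10 kb, and the clustering ratio ranged from 2.10 (100 kb) to 6.79 (2 kb). Alternatives that needed mm9 lengths, sequence or annotation were not run. Unknown depth leaves open how many further regions fell below the caller's threshold.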

Other observations

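The tests of close neighbours within 1 Mb windows and of the windows beside the densest one were set out before their results were seen. Merging within 1 kb was among the alternatives fixed before the data were examined, but its use as a test of split regions was written down afterwards. The remaining tests of this part were chosen after the pattern they bear on was seen.

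Regions with a neighbour within 10 kb were wider than the rest. Their median width was 830 bp (quartiles 693 and 957 bp, 401 regions) against 772 bp (636 and 915 bp, 2788 regions), a difference of 58 bp (two-sided permutation within chromosomes, p = 3e-05, Benjamini-Hochberg adjusted over 2 measures p = 6e-05). That test shuffles regions singly, although the 401 come from 193 clusters; with only the first region of each cluster the difference was 71 bp (median 843 bp, adjusted permutation p = 0.00062). Their median score was 66.06 against 64.12, a difference of 1.94 that did not pass the threshold (adjusted permutation p = 0.101, and 0.545 with 1 region per cluster). The longest stretches without any region were on X, where 34.97 Mb from 102265981 to 137240673 and 22.2 Mb from 68307405 to 90506027 held none; the longest on an autosome was 16.52 Mb on chromosome 18, from 15972719 to 32494972. Stretches of 10 Mb with the highest numbers, picked after their values were seen, were chromosome 3 from 100000001 to 110000000 with 35 regions and chromosome 18 from 30000001 to 40000000 with 33, the latter window including the end of that empty stretch.

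The low density on X is hard to ascribe to a chance arrangement of region-rich stretches, since shuffling 10 Mb bins gave an adjusted p of 0.0002. What stays open, untested, is a lower dose of X from a single copy, 1 of 2 copies being inactive, poorer mapping of reads to X, or fewer open regions there. If the list was called against the other condition, few regions on X would instead mean few differences there. The score cannot decide between these, since its relation to the FAIRE signal and to the control is not known here.

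The tables argue against each of the following as the whole account of the close neighbours. Placing each region at random within its own 1 Mb window, which keeps any unevenness over megabases, still left a ratio of observed to random of 2.584, and merging regions within 1 kb, which undoes only splits of a broad region by gaps of up to 1 kb (41 of the 208 gaps within 10 kb), left 3.865. Broad regions split by gaps of 1 to 10 kb stay open. Also open is that sites of the same gene or regulatory domain, open or differing between the conditions, lie together, which needs gene annotation. Unevenly mappable sequence below 1 Mb that confines the regions stays open as well.

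The densest window, on chromosome 5 from 91000001 to 92000000, exceeded all 1000 random placements (permutation p over placements = 0.001). Those placements assumed a uniform density along each chromosome, which the list as a whole did not show, so the p is not particular to this window. They also did not keep close neighbours together, whereas most regions of this window lay within 10 kb of another. Close or split regions were thus counted singly. The chromosome 13 window from 111000001 to 112000000, with 11 regions, also exceeded the random maximum of 10. A copy gain spanning 3 Mb or more could raise such a count in adjoining windows too. The neighbouring windows held 0 and 1 regions, where the autosomal mean was 1.33 per window. These counts cannot exclude such a gain, since 44.1% of autosomal windows held no region. How a gain would alter the counts also depends on the control, which is unknown. A copy gain of any length stays open, as does a locus with many open sites or many differences between the conditions. Input coverage or gene annotation would bear on these.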
